A study of Mus musculus with 6 samples.

How the data were processed

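Total RNA of the olfactory bulb of 6 mice, 3 per diet, was made into stranded total RNA libraries and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. Per the submitters' processing notes, the authors used Trimmomatic, STAR and Cuffnorm with the mouse genome mm10 (GRCm38.p6); versions and the annotation release are not given in the sources used here. The deposited table holds 1 value per gene and mouse, printed in steps of 0.1. The header names no unit, and the values were read as FPKM (fragments scaled by transcript length and library size, normalized between libraries), the usual output of Cuffnorm, which the labels name for the authors' processing. The column totals ran from 666738 to 908422, while those of protein-coding genes ran from 307210 to 317865. FPKM are not counts, so no count model was used, and the number of fragments behind a value is unknown. In short RNAs of 2 lengths values fell in whole steps. Apart from values at the lowest level of a library and length, 34 values lay under 10 times that level, and 34 of them were within 0.1 steps of a whole multiple, where chance gives 20%. This test was chosen after the values were seen. The value of 1 fragment of Gm24888 was taken from other short RNAs of its length in 2 libraries in which the lowest value was repeated, scaled to the other libraries by the step of a second length. Of the 55331 gene IDs, 54583 were found with the same version in GENCODE vM21, the annotation of the same genome build (GRCm38), from which gene positions, strands and overlaps were taken.

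Groups were taken from the sample titles, and each title names a separate mouse. The comparison was HFD against NFD, with no covariate. Genes with a mean of at least 1 FPKM over the 6 mice were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) on log2(FPKM + 1), two-sided, with Benjamini-Hochberg adjustment over the 15763 genes and a threshold of 0.05. The pseudocount of 1 means that fold changes understate those of low genes. Every p-value in the text that is not called exact comes from limma, including camera and fry. An exact two-sided permutation test of 3 against 3 mice cannot go below p = 0.1. The test, the 45 gene lists and the rule for named genes were fixed before the data were examined. The lists cover pathways of lipid, glucose and energy metabolism, stress, immunity, synapses and feeding, and markers of bulb cell types and of neighbouring tissues; 1 of them is a check of sex-linked genes without a test. The other 44 were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 44, and again with an estimated correlation, on ranks and with fry.

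By the naming rule, genes past the threshold were to be named first, up to 12 per direction. Where fewer passed, the genes with the smallest unadjusted p among those without overlap between the groups filled up to 6 per direction. Predicted genes, ribosomal, small RNA and pseudogene rows were left out of the naming. Up to 2 members with the smallest p were to be named in each list without a member past the threshold. Other genes are said in the text to have been chosen after their values were seen, and this holds for Omp, Mbp and Rpl27a as well.

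The fit was tested on simulated data for 15426 genes with the spread of the real ones, of which 200 were changed. With 3 mice per group it recovered 79% of genes changed by log2 1 and 98% of those changed by log2 2 among genes of at least 5 FPKM, with 6 false calls, and called 1 gene and 0 lists when nothing was changed. The 200 genes were changed at once, and many changed genes ease the Benjamini-Hochberg threshold. These shares therefore do not carry over to the real comparison, where 1 gene passed, and fewer changed genes were not simulated. A list raised by 0.4 was recovered by camera at an adjusted p of 1.72e-08. The simulated genes varied independently of each other, while the real immediate early genes had an estimated correlation of 0.60. The absence of false list calls and this recovery therefore say nothing of real lists whose members move together. The median SE of a log2 fold change in the real data was 0.16. Alternatives were other pseudocounts, filters, scalings, variance models, a replicate block, each mouse left out in turn, a smaller set of genes and other list tests. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining steps. The protein measurements that the series description mentions were not used here.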

Results

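RNA from the olfactory bulb, the forebrain region that receives the axons of the nasal sensory neurons, was sequenced in mice kept on 2 diets. The normal fat diet (NFD) had a fat content of 3.5% and a carbohydrate content of 8%. The high fat diet (HFD) had a fat content of 45% and a carbohydrate content of 35%, and protein was 20% in both. The HFD values fill the whole diet and the NFD values do not. The 2 sets may therefore be on unlike bases, and their carbohydrate contents cannot be compared safely. Feeding began at 2 months of age and lasted 4 months. Each group had 3 separate mice, so the table held 6 libraries, named here NFD 1 to 3 and HFD 1 to 3. It listed 55331 genes as FPKM, and 27639 of them were at 0 in all 6 mice. The 15763 genes with a mean of at least 1 FPKM were tested. The number of fragments per library is unknown. Short RNAs of 1 length took values in whole steps, which differed 1.33-fold between NFD 3 (smallest step) and HFD 3 (largest). The step was 427.4, 467.2 and 392.3 FPKM in NFD 1 to 3 and 468.2, 474.7 and 522.1 in HFD 1 to 3. Every HFD step was thus larger than every NFD step, though HFD 1 lay close to NFD 2. At a second length the steps were 5.8, 5.7 and 5.1 in NFD and 5.8, 6.3 and 6.5 in HFD. The step holds relative depth together with any scaling between libraries, and these cannot be told apart here. The effect of a depth difference between the diets was not tested. Between libraries, log2(FPKM + 1) of the tested genes correlated across genes at 0.937 to 0.951 within groups and at 0.926 to 0.961 between groups. Genes are not independent replicates. The Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y were expressed in every mouse, with Uty at 19.0 ± 1.40 FPKM in NFD and 24.9 ± 2.25 in HFD (SD, n = 3 each). Xist lay between 0 and 0.1 FPKM, so both groups had the pattern of male tissue.

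The comparison asked how gene expression in the bulb differed after the high fat diet. As a group, immediate early genes, which neurons switch on soon after activity, were lower in HFD by a median log2 fold change of -0.39 over 20 measured members (adjusted p = 0.631 with an estimated correlation). The groups overlapped, and the median was -0.16 without NFD 3. Genes of fatty acid synthesis and desaturation were lower as well, at a median of -0.19 over 20 members (adjusted p = 0.503 with an estimated correlation). Markers of astrocytes, oligodendrocytes, mitral and tufted cells and olfactory sensory neurons were also lower as groups, and interferon-stimulated genes were higher by a median of 0.28. None of these lists passed with an estimated correlation (adjusted p = 0.503 to 0.631 with an estimated correlation). Without NFD 3 the sensory neuron list had a median of 0.03 (adjusted p = 0.796), and without HFD 2 the interferon list had one of 0.07 (0.735). Among single genes without overlap between the groups, Dapl1, Ecm1 and Cyp4f15 were lower and Zfp407, Fam92a and Pycard were higher in HFD, but none of these 6 passed the test. The only gene past the threshold was Gm24888, a small nucleolar RNA listed at 0 in all NFD mice.

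Gm24888 (ENSMUSG00000077575.1) lies on the plus strand of chromosome 7 from 109521280 to 109521409 (GRCm38), inside an intron of Rpl27a, a ribosomal protein gene of the same strand. It overlaps the microRNA locus Gm47284 on that strand, so the assignment of fragments between the 2 is uncertain. It falls outside the rule by which genes were named and was chosen after its values were seen. It was listed at 56.9, 30.1 and 63.8 FPKM in HFD 1, 2 and 3 (limma, adjusted p = 0.000435). At its length of 130 bases, 1 fragment was worth about 28.1 to 31.5 FPKM in these libraries, so the values correspond to 2, 1 and 2 fragments. Its host Rpl27a was at 103 ± 8.86 FPKM in NFD and 113 ± 6.22 in HFD (SD, n = 3 each; limma, adjusted p = 0.723).

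At an unadjusted p under 0.05, 839 genes were higher and 388 lower in HFD, against 788 expected by chance in both directions together, and the smallest adjusted p after that of Gm24888 was 0.622 (limma). The share of higher genes among them was 68.4% on the deposited scale, 59.8% with upper quartile scaling, 56.3% with quantile normalization, 55.3% with median of ratios scaling and 43.2% on the TPM scale. TPM scaling divides by the column total, of which the single gene Bc1 held from 10.9% (HFD 2) to 22.5% (NFD 1). How far such genes set the share on that scale was not tested. The groups did not overlap for 2108 genes, 13.4% of those tested, where chance gives 10%. Leaving out 1 mouse moved the count of genes past the threshold to 7 without NFD 1, 7 without NFD 2, 2 without NFD 3, 5 without HFD 1 and 3 without HFD 2. Without HFD 3 it was 1.

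Each of the genes with the smallest p among those without overlap had an adjusted p of 0.622 (limma). Their fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Dapl1, a gene named for its likeness to a death-associated protein (ENSMUSG00000026989.5, chromosome 2, 59484653 to 59505020, plus strand, GRCm38), was at 2.63 ± 0.379 FPKM in NFD and 0.533 ± 0.208 in HFD (SD, n = 3 each). This is a log2 fold change of -1.25 with an SE of 0.21. Ecm1, a secreted extracellular matrix protein (ENSMUSG00000028108.15, chromosome 3, 95734147 to 95739569, minus strand), went from 3.50 ± 0.265 to 1.33 ± 0.231 FPKM. Cyp4f15, a cytochrome P450 of the family that hydroxylates fatty acids and eicosanoids, was at 12 ± 0.950 FPKM in NFD and 7.43 ± 0.702 in HFD. Log2 fold changes of Atad3aos, Ubtd2 and Oscp1 were -1.22, -0.81 and -0.54. Exons of Atad3aos overlap those of Vwa1 on the opposite strand, and whether the counting used the strand is not given in the sources used here, so its level is uncertain. In the other direction, Zfp407, a zinc finger gene (ENSMUSG00000048410.17, chromosome 18, 84128027 to 84589725, minus strand), was at 15.6 ± 1.10 FPKM in NFD and 22.5 ± 0.200 in HFD. Its log2 fold change was 0.50 with an SE of 0.10. Fam92a, which has a part in building cilia, was at 24.6 ± 1.22 and 34.6 ± 1.90 FPKM. Pycard, the adaptor protein of inflammasomes (ENSMUSG00000030793.4, chromosome 7, 127989708 to 127993867, minus strand), was at 0.933 ± 0.208 and 2.80 ± 0.557 FPKM, close to the lower limit of testing. Lrch3, Spopl and Lrba had log2 fold changes of 0.49, 0.56 and 0.36. The annotated spans of the 6 higher genes ran from 4160 (Pycard) to 558013 bases (Lrba). Those of the 6 lower genes ran from 5423 (Ecm1) to 61318 (Ubtd2). Whether fold changes follow gene length was not tested. Exons of Zfp407, Pycard, Lrch3, Spopl and Lrba overlap exons of genes on the opposite strand, and those of Ecm1 a short RNA of its own strand, which makes their levels less certain.

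**Figure D1:**
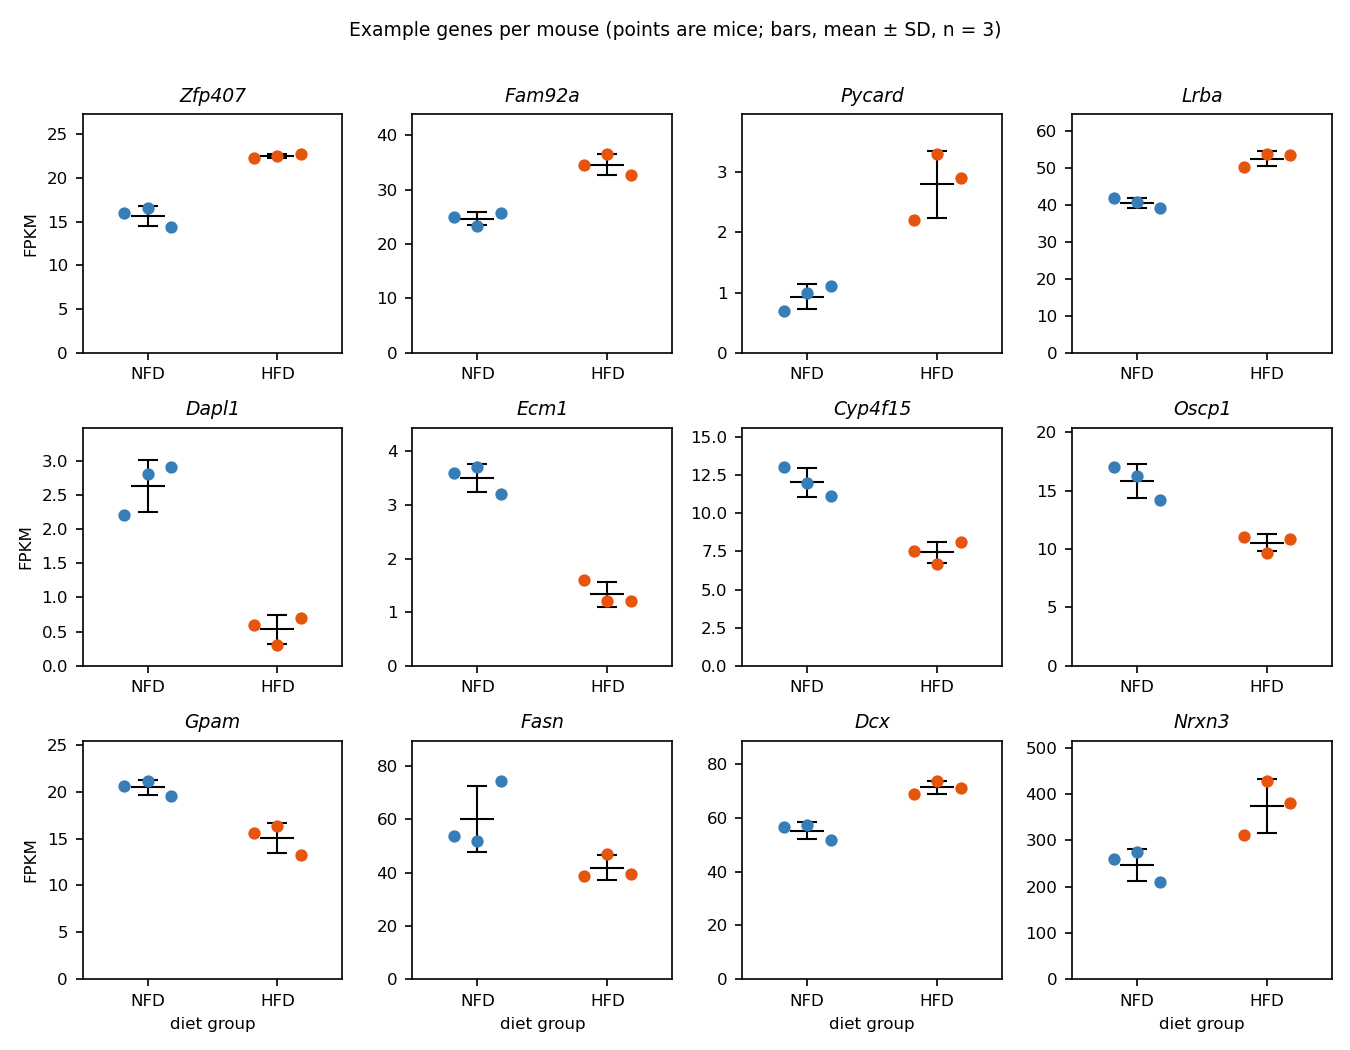
FPKM (vertical axes, from 0) of 12 genes in the 3 NFD mice (blue) and 3 HFD mice (orange); points are mice and bars are means ± SD. In each panel the 3 HFD values lie on one side of the 3 NFD values, and no gene shown passed the adjusted test (smallest adjusted p 0.622). Gpam, Fasn, Dcx and Nrxn3 were named as list members with a small p. The other genes shown were picked for this lack of overlap, so the separation follows from the choice of genes.

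Of 44 gene lists with at least 5 measured members, 15 passed camera's test with its preset correlation of 0.01, 14 of them lower and 1 higher in HFD. None of the 44 passed with an estimated correlation (smallest adjusted p = 0.503 with an estimated correlation). None passed by fry's test of a shared direction (smallest adjusted p = 0.463), and 14 passed on ranks. In every list, 0 members passed over all genes tested. One list, inflammatory cytokines and NF-kB signalling, held a member past the threshold adjusted over the list alone, which was Pycard. List means per mouse did not overlap between the groups for 6 lists, where chance gives 10% of lists. Members are counted as higher or lower by the sign of their fold change.

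Immediate early genes had 19 of 20 measured members lower in HFD (camera, adjusted p = 5.46e-06; adjusted p = 0.631 with an estimated correlation), and 0 members passed adjusted over the list alone. By the naming rule, Jund went from 37.1 ± 2.96 to 29.9 ± 2.78 FPKM and Btg2 from 13.2 ± 1.00 to 10.3 ± 0.839 (SD, n = 3 each). Fos, Egr1 and Arc, chosen after their values were seen, were at 33.3 ± 8.79, 42.7 ± 20.8 and 58.9 ± 20.9 FPKM in NFD and at 21.5 ± 4.90, 27.1 ± 7.19 and 38.3 ± 8.06 in HFD. The list mean was highest in NFD 3 and lowest in HFD 3, and NFD 1 lay below HFD 1 and HFD 2. The median log2 fold change was -0.16 without NFD 3 (adjusted p = 0.00802), -0.30 without HFD 3 and -0.70 without NFD 1. In a fit chosen after seeing the data, without NFD 3 and HFD 3, the call was lost and the median was -0.05 (adjusted p = 0.278). Over the 6 mice, the immediate early list mean followed that of mitral and tufted cell markers (Pearson r = 0.967). That relation was picked out after the results were seen.

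Of the genes of fatty acid synthesis and desaturation, 15 of 20 measured members were lower (camera, adjusted p = 0.000756; adjusted p = 0.503 with an estimated correlation), and the list means of the groups did not overlap. Those of astrocyte and oligodendrocyte precursor markers, also lower in HFD, did not overlap either. Whether the fatty acid genes followed these markers across mice was not tested. Fasn, the fatty acid synthase, was at 60.1 ± 12.5 FPKM in NFD and 41.8 ± 4.58 in HFD, and Gpam, which starts glycerolipid synthesis at the mitochondrial membrane, was at 20.5 ± 0.808 and 15.1 ± 1.61 (SD, n = 3 each). Fads2 and Scd2, desaturases chosen after their values were seen, had log2 fold changes of -0.27 and -0.25. The call was kept in each fit without 1 mouse, with adjusted p between 0.000189 and 0.00802, and in the fit without NFD 3 and HFD 3 (adjusted p = 0.0191), which ended 9 of the other list calls. Genes of fatty acid oxidation and ketone metabolism had a median of -0.12 and did not pass (adjusted p = 0.0776). Ucp2, a mitochondrial carrier, went from 8.47 ± 3.03 to 4.87 ± 0.751 FPKM. Cholesterol synthesis and uptake had a median of -0.02 (adjusted p = 0.413), with Dhcr24 and Srebf2 at log2 fold changes of -0.36 and -0.26.

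Several lists of cell types were lower in HFD. Astrocyte markers were lower in 13 of 16 members (camera, adjusted p = 0.00861; adjusted p = 0.503 with an estimated correlation). Ntsr2, a neurotensin receptor, was at 30.1 ± 2.29 FPKM in NFD and 24 ± 0.115 in HFD, and Mlc1 at 41.6 ± 2.57 and 35.0 ± 1.97 (SD, n = 3 each). The call was lost without HFD 2 (median -0.06, adjusted p = 0.0945). Oligodendrocyte and myelin markers were lower in 16 of 19 members (camera, adjusted p = 0.00861; adjusted p = 0.631 with an estimated correlation). Olig1 and Olig2, transcription factors of the lineage, had log2 fold changes of -0.32 and -0.43. The median of -0.18 was -0.29 without NFD 3 and -0.33 without HFD 3. The call was lost without NFD 1 (median -0.02, adjusted p = 0.121), NFD 2 (-0.17, 0.0511), HFD 1 (-0.09, 0.0952) or HFD 2 (-0.06, 0.114), and with a minimum mean of 5 FPKM (adjusted p = 0.108). HFD 3 and NFD 3 went against their groups, with Mbp, the myelin basic protein, at 692 FPKM in HFD 3 and 352 in NFD 3 against 553 and 480 in NFD 1 and 2 and 390 and 335 in HFD 1 and 2. Oligodendrocyte precursor markers were lower in 8 of 10 members, with Bcan at -0.34 and Gpr17 at -0.40 (camera, adjusted p = 0.0268; adjusted p = 0.503 with an estimated correlation). That call was lost without NFD 2 (adjusted p = 0.0637), NFD 3 (0.0516) or HFD 1 (0.0855). It was lost as well with a minimum mean of 5 FPKM (0.224) and without predicted, ribosomal, small RNA and pseudogene genes (0.0502).

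Markers of mitral and tufted cells, the output neurons of the bulb, were lower in 15 of 16 members (camera, adjusted p = 0.00861; adjusted p = 0.631 with an estimated correlation). Slc17a7, a vesicular glutamate transporter, was at 123 ± 32.8 FPKM in NFD and 83.5 ± 15.1 in HFD, and Olfm1 at 144 ± 25.5 and 110 ± 7.25 (SD, n = 3 each). The median of -0.18 was -0.28 without NFD 1, and the call was lost without NFD 2 (adjusted p = 0.0637) or NFD 3 (0.145). Presynaptic genes were lower in 24 of 28 members (camera, adjusted p = 0.00861; adjusted p = 0.631 with an estimated correlation). Syngr1 had a log2 fold change of -0.35, while Nrxn3, a presynaptic adhesion protein, was at 247 ± 34.2 FPKM in NFD and 374 ± 58.6 in HFD. The median was -0.13, and -0.07 without NFD 3. Without NFD 2 (adjusted p = 0.055) or NFD 3 (0.137) this call was lost. Olfactory sensory neuron genes, listed for the nasal neurons whose axons enter the bulb, were lower in 16 of 18 members (camera, adjusted p = 0.00861; adjusted p = 0.631 with an estimated correlation). Lhx2 and Nrp2 were at -0.37 each. Whether these transcripts came from axons or from other cells was not tested. The list median of -0.37 was 0.03 without NFD 3 (adjusted p = 0.796) and -0.20 without HFD 2 (0.0569), where the call was lost, as it was with a minimum mean of 5 FPKM (0.0653). Genes of the support cells of olfactory and respiratory epithelium had a median of -1.03 over 10 members (camera, adjusted p = 0.0103; adjusted p = 0.631 with an estimated correlation), and NFD 3 carried the difference. Cyp2g1, an olfactory mucosa cytochrome P450 chosen after its values were seen, was at 44.0 FPKM there and at 0.2 or less in the other 5 mice. By the naming rule, Ugt2a2 was at 11.4 FPKM in NFD 3 and at 0.3 or less in the other 5 mice. Exons of Ugt2a2 overlap those of Ugt2a1 and Gm43638 on the same strand, so its level is uncertain. Foxj1 went from 3.10 ± 0.854 to 1.57 ± 0.551 FPKM (SD, n = 3 each). Foxj1 was at 3, 2.3 and 4 FPKM in NFD 1 to 3 and at 2.1, 1.6 and 1 in HFD 1 to 3. Its groups did not overlap, with or without NFD 3, but it did not pass the test (limma, adjusted p = 0.622). Without NFD 3 the list was on the higher side (median 0.12, adjusted p = 0.956), and without HFD 2 (0.0569) or with a pseudocount of 0.01 (0.0516) it did not pass. Its median was -1.74 without NFD 1 and -1.68 without NFD 2. NFD 3 also had the highest Omp, the olfactory marker protein, at 76.2 FPKM against 21.8 to 43.2.

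**Figure D2:**
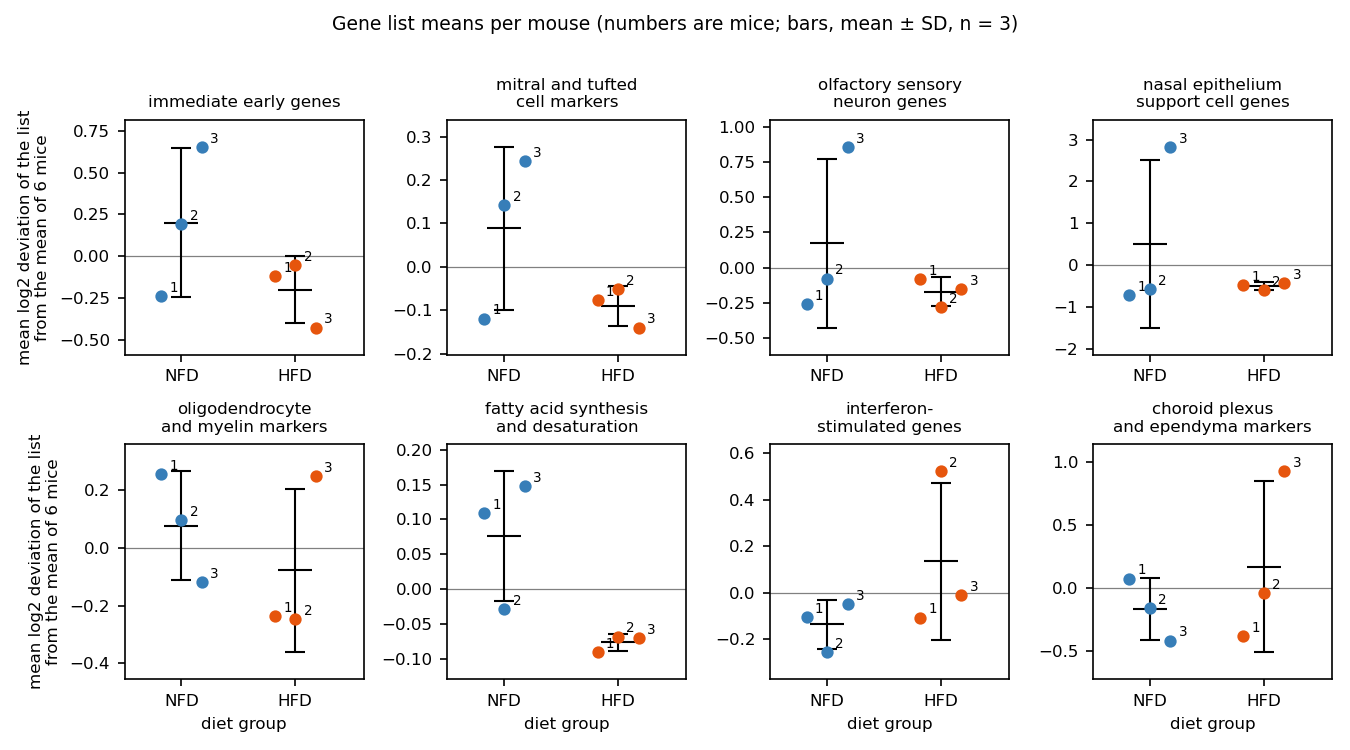
Mean deviation of 8 gene lists from the mean of the 6 mice (vertical axes, log2 units, scaled per panel), by diet group; points are mice, numbered, and bars are means ± SD. NFD 3 stands highest for epithelium support genes (2.82) and immediate early genes (0.65), HFD 2 for interferon-stimulated genes (0.52) and HFD 3 for choroid plexus markers (0.93).

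Interferon-stimulated genes were higher in 15 of 16 members (camera, adjusted p = 0.048; adjusted p = 0.631 with an estimated correlation). Stat1, a transcription factor of interferon signalling, was at 9.27 ± 1.72 FPKM in NFD and 13.8 ± 0.40 in HFD, and Irf9 at 3.97 ± 1.5 and 5.50 ± 1.25 (SD, n = 3 each). Exons of Stat1 overlap those of Gm28177, and exons of Irf9 those of Rnf31, each on the same strand, so the levels of both genes are uncertain. HFD 2 stood highest, with Ifit3, chosen after its values were seen, at 20.4 FPKM against 6.0 to 7.7 in the other mice. The call was lost without HFD 2 (median 0.07, adjusted p = 0.735), NFD 1 (0.0721) or NFD 2 (0.135). It depended on the pseudocount, as it was lost with 0.1 (adjusted p = 0.0541) and 0.01 (0.0582), and was lost with a minimum mean of 5 FPKM (0.167). Antigen presentation did not pass (median 0.16, adjusted p = 0.515). B2m, the light chain of class I molecules, went from 72.9 ± 6.01 to 93.4 ± 7.98 FPKM, and Tapbp from 9.23 ± 1.96 to 6.20 ± 0.529. Inflammatory cytokines and NF-kB signalling (median 0.05, adjusted p = 0.736), microglia markers (0.04, 0.943) and reactive astrocyte genes (-0.07, 0.515) did not pass either. Itgam and Ctss, both expressed by microglia, had log2 fold changes of -0.46 and 0.22; exons of Itgam and Tapbp overlap those of other genes of their strand.

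Glycolysis and hypoxia genes were lower in 21 of 25 members with a median of -0.09, among them Hk1 at -0.25 (camera, adjusted p = 0.00861; adjusted p = 0.631 with an estimated correlation). It did not pass without NFD 2 (adjusted p = 0.0839) or without NFD 3 and HFD 3 (0.0531). Feeding-related peptides and receptors were lower in 19 of 24 members with a median of -0.13 (camera, adjusted p = 0.0287; adjusted p = 0.503 with an estimated correlation). Cartpt, an appetite-related peptide, was at 7.80 ± 3.20 FPKM in NFD and 3.80 ± 1.56 in HFD, and Cck at 163 ± 15.2 and 139 ± 7.87 (SD, n = 3 each). The median was -0.08 without NFD 3 and -0.08 without HFD 3. Without NFD 2 (adjusted p = 0.0833) or HFD 2 (0.135) the list did not pass, nor without predicted, ribosomal, small RNA and pseudogene genes (0.0837). Unfolded protein response genes had a median of -0.08, with Xbp1 at -0.25 (camera, adjusted p = 0.0463; adjusted p = 0.631 with an estimated correlation). They did not pass without NFD 2 (median -0.02, adjusted p = 0.236), HFD 3 (-0.01, 0.32) or HFD 2 (0.078), and the median was -0.13 without HFD 1. Nor did they pass with no filter (0.0712), a minimum mean of 5 FPKM (0.191), the replicate block (0.0537) or without predicted, ribosomal, small RNA and pseudogene genes (0.134). Autophagy and lysosome genes had a median of -0.04, with Sqstm1 at -0.17 (camera, adjusted p = 0.048; adjusted p = 0.631 with an estimated correlation). Pericyte and smooth muscle markers had one of -0.18, with Rgs5 at -0.24 (camera, adjusted p = 0.0486; adjusted p = 0.631 with an estimated correlation). The autophagy call was lost without NFD 1 (adjusted p = 0.144), NFD 2 (0.135), HFD 1 (0.0898) or HFD 2 (0.0945), with medians of -0.07 without NFD 1 and -0.08 without NFD 3. It was lost with a minimum mean of 5 FPKM (0.0667), quantile normalization (0.0542), the replicate block (0.0744) and without predicted, ribosomal, small RNA and pseudogene genes (0.192). The pericyte call was lost without NFD 2 (0.0637), NFD 3 (0.397), HFD 1 (0.0952) or HFD 2 (0.0995), and the median was -0.29 without NFD 1. It was kept in 5 of 21 alternatives. Upper quartile (adjusted p = 0.0589), median of ratios (0.0645) and TPM scaling (0.114) ended it, as did no filter (0.195), the replicate block (0.0537), ranks (0.0527) and leaving out predicted, ribosomal, small RNA and pseudogene genes (0.115).

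The other lists did not pass with the preset correlation. Insulin and leptin signalling had a median of -0.06 (adjusted p = 0.0817), with the kinase gene Akt2 at 23.9 ± 2.89 FPKM in NFD and 17.3 ± 1.46 in HFD. Jak2, which signals from the leptin receptor, was at 19.1 ± 1.10 and 23.2 ± 1.56 (SD, n = 3 each). Circadian clock genes (median -0.07, adjusted p = 0.0973) held Ciart at -0.60 and Clock at 0.29, and glucocorticoid-responsive genes (-0.11, 0.0973) held Arrdc2 at -0.53. Insulin and leptin signalling passed without NFD 1 (adjusted p = 0.0115), and glucocorticoid-responsive genes without NFD 1 (0.0209) or HFD 1 (0.00663). Among neuronal lists, dopaminergic periglomerular genes (-0.14, 0.106), cortex and anterior olfactory glutamatergic markers (-0.14, 0.106), and granule cell and GABAergic interneuron markers (0.02, 0.814) did not pass. Nor did glutamate receptors and postsynaptic genes (0.01, 0.671), GABA receptors and inhibitory synapse genes (0.05, 0.922) or voltage-gated channels (0.07, 0.814). Members with small unadjusted p in them were Nr4a2 at a log2 fold change of -0.78, Nptx1 at -0.43, Grik2 at 0.39, Grin2a at 0.37 and Scn1b at -0.32. Neuroblast and proliferation genes had a median near 0 (adjusted p = 0.885), with Dcx, a microtubule protein of migrating neuroblasts, at 55.2 ± 3.12 FPKM in NFD and 71.3 ± 2.40 in HFD.

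Endothelial markers (median -0.11, adjusted p = 0.13), olfactory ensheathing cell genes (-0.14, 0.178), meningeal and fibroblast markers (-0.02, 0.268), choroid plexus and ependyma markers (0.09, 0.922) and erythroid and leukocyte markers (0.07, 0.495) did not pass. Ensheathing cell genes passed as lower without NFD 1 (adjusted p = 0.0129) and meningeal markers without NFD 2 (0.0403). Ttr, the transthyretin of the choroid plexus, was at 86.8 FPKM in HFD 3 and at 1.6 to 6.1 in the other 5 mice. Cytosolic ribosomal proteins (0.07, 0.106), nuclear-encoded oxidative phosphorylation (0.02, 0.943), mitochondrially encoded transcripts (0.08, 0.499), and mitochondrial dynamics (0.04, 0.814) did not pass. Nor did antioxidant and NRF2 targets (-0.01, 0.413), heat shock genes (-0.02, 0.495), apoptosis genes (-0.04, 0.42) or amyloid, tau and neurodegeneration genes (-0.07, 0.294). Ribosomal proteins passed as higher without NFD 2 (adjusted p = 0.00305) or HFD 2 (0.000626) and with no filter (0.0401). Examples were Nqo1, an NRF2 target, at 3.90 ± 0.50 FPKM in NFD and 5.93 ± 1.01 in HFD, Sdhc at a log2 fold change of -0.33, Pink1 at -0.24, Sorl1 at -0.27 and Cldn5 at -0.46. In 7 lists, none of them past the threshold, the test's direction was lower while the median or the mean was above 0. Camera compares a list with the remaining genes, and the median over all genes was 0.02.

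**Figure D3:**
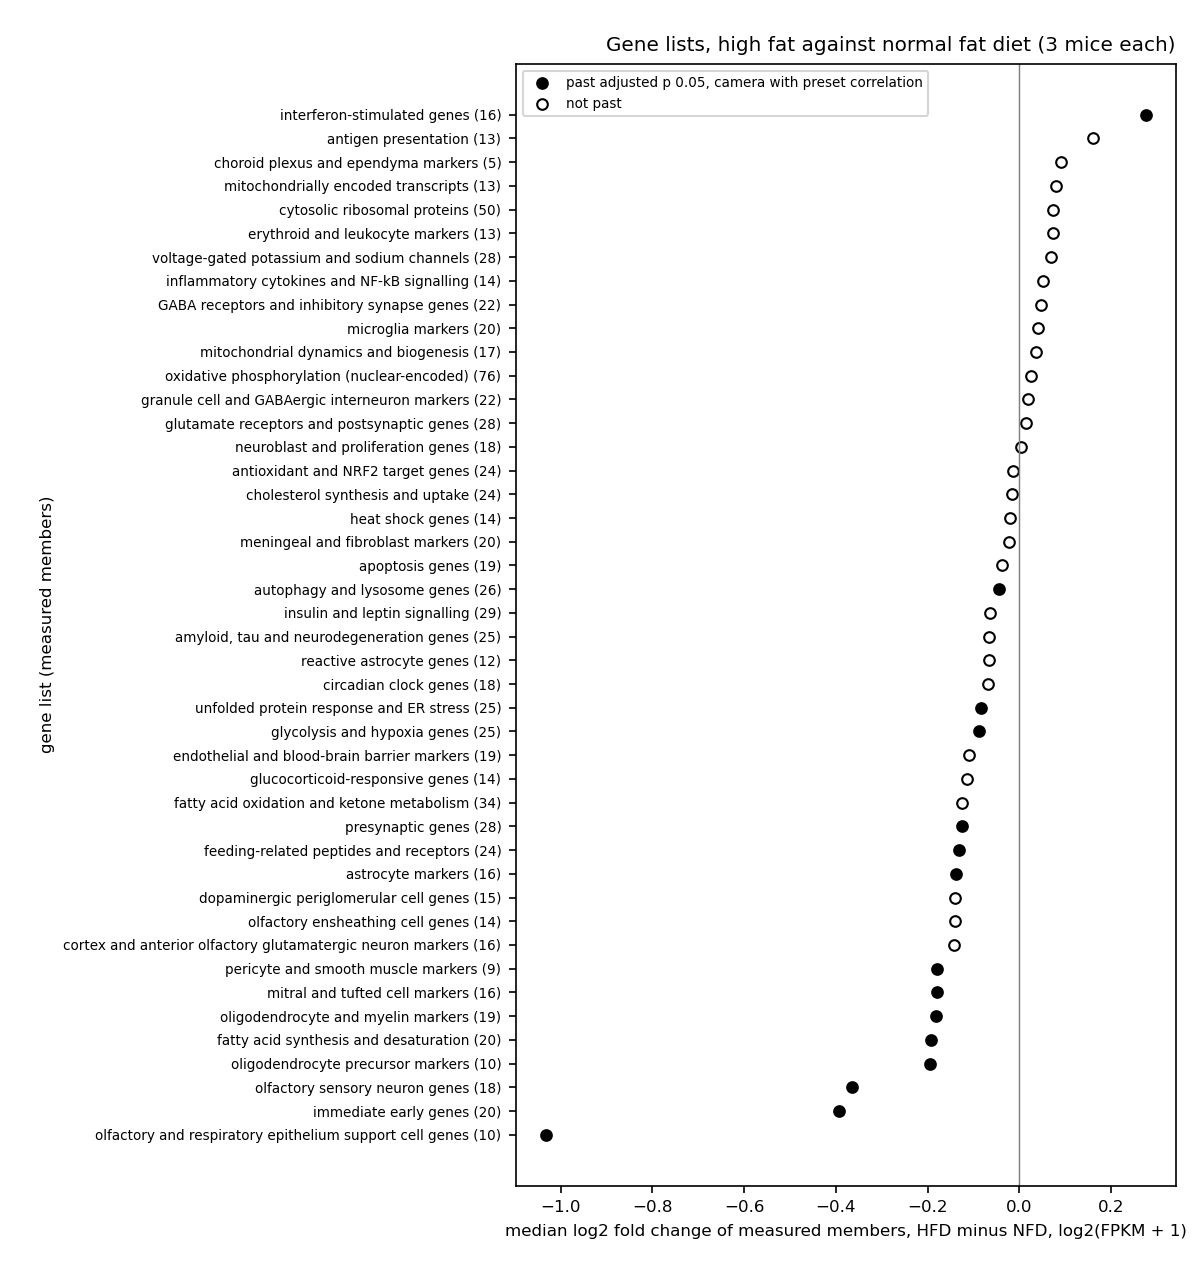
Median log2 fold change (horizontal axis, HFD minus NFD on the log2(FPKM + 1) scale) of the measured members of each of 44 gene lists (vertical axis, number of members in brackets), 3 mice per group; filled points passed camera's test with the preset correlation. The 15 filled points run from -1.03 for epithelium support genes to 0.28 for interferon-stimulated genes, and none was kept with an estimated correlation.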

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

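The fits without NFD 3 and HFD 3 together, with the olfactory sensory neuron list mean as a covariate, and with a mean-variance trend in camera were chosen after seeing the data. Gm24888 was past the threshold in 18 alternatives, with an adjusted p between 2.98e-06 and 0.0172, and not with 2 mice per group (adjusted p = 0.168). Short RNAs were not tested in the fit without predicted, ribosomal, small RNA and pseudogene rows. The count of genes past the threshold (1) was 0 in that fit, where limma gave 495 higher and 387 lower genes at an unadjusted p under 0.05. It was 0 with 2 mice per group, with 462 higher and 379 lower. It was 2 with the covariate, 1 to 7 without 1 mouse, 1 at an adjusted p under 0.1 and 283 (188 higher, 95 lower) at an unadjusted p under 0.05 with a fold of at least 1.5. Of the counts at an unadjusted p, lower genes were 612 with no filter, since more genes were tested, and higher genes were 252 on the TPM scale. Without 1 mouse they were 537 to 1150 higher and 286 to 634 lower. The count of lists past the threshold (15) was 7 with a minimum mean of 5 FPKM, 7 with the covariate, 6 with 2 mice per group, 7 to 15 without 1 mouse, and 0 with an estimated correlation and by fry. The cause was not tested where no smaller set of mice or genes explains it. Over all lists and alternatives, 782 comparisons kept their direction and their side of the threshold, 103 lost the call, 8 gained it and 69 changed direction. The 782 include lists that did not pass and stayed so. All 103 losses fell on the 15 lists that passed, each with 21 or 22 alternatives. Their calls were kept in 5 (pericytes) to 20 (fatty acid synthesis) of these. Of these 69, 1 was a list past the threshold, the epithelium support list without NFD 3 (adjusted p = 0.956, and 0.00164 to 0.956 without 1 mouse), and 68 were lists that did not pass. With 2 mice per group the direction changed for mitochondrially encoded transcripts (adjusted p = 0.719), ribosomal proteins (0.199), microglia (0.634), granule cells (0.634), neuroblasts (0.257), ensheathing cells (0.43), meninges (0.31), choroid plexus (0.329), apoptosis (0.735) and glucocorticoid-responsive genes (0.992). With the covariate it changed for microglia (0.918), neuroblasts (0.85), ensheathing cells (0.959), meninges (0.477) and choroid plexus (0.708), and on the TPM scale for microglia (0.841). Nuclear-encoded oxidative phosphorylation changed direction on ranks (0.956), with camera's trend (0.955), by fry (0.901), with a minimum mean of 5 FPKM (0.963), with no filter (0.825), with quantile normalization (0.91) and without predicted, ribosomal, small RNA and pseudogene rows (0.571). By fry, mitochondrial dynamics (0.901), granule cells (0.913), neuroblasts (0.905), GABA receptors (0.901) and voltage-gated channels (0.905) changed. With a minimum mean of 5 FPKM inflammatory cytokines (0.963), antigen presentation (0.703), granule cells (0.977) and neuroblasts (0.931) did, and with no filter inflammatory cytokines (0.746), choroid plexus (0.878) and GABA receptors (0.941). With quantile normalization granule cells (0.979) and GABA receptors (0.979) did. Without the predicted and other rows, mitochondrial dynamics (0.841), granule cells (0.86), neuroblasts (0.826), GABA receptors (0.757) and voltage-gated channels (0.841) did. Leaving out 1 mouse changed the direction of 15 of the lists that did not pass, with adjusted p without 1 mouse from 0.128 to 0.95 (oxidative phosphorylation), 0.0945 to 0.811 (mitochondrially encoded transcripts), 0.000626 to 0.796 (cytosolic ribosomal proteins), 0.362 to 0.909 (microglia), 0.417 to 0.991 (inflammatory cytokines and NF-kB signalling), 0.0898 to 0.827 (antigen presentation), 0.121 to 0.937 (granule cell and GABAergic interneuron), 0.302 to 0.937 (neuroblast and proliferation), 0.0403 to 0.504 (meningeal and fibroblast), 0.495 to 0.962 (choroid plexus and ependyma), 0.146 to 0.921 (erythroid and leukocyte), 0.137 to 0.851 (antioxidant and NRF2 target), 0.219 to 0.988 (glutamate receptors and postsynaptic), 0.458 to 0.892 (GABA receptors and inhibitory synapse), 0.484 to 0.965 (voltage-gated potassium and sodium channels). Of the named genes' comparisons, 1955 kept both, 1 lost the call (Gm24888 with 2 mice per group) and 0 changed direction. Apart from Gm24888, these genes had no call to lose and were picked for a small p in these same data. That they kept both was therefore largely set in advance and is no measure of stability. With 2 mice per group the calls of immediate early genes (0.278), mitral and tufted cells (0.31), presynaptic genes (0.204), sensory neurons (0.736), epithelium support (0.782), oligodendrocyte precursors (0.143), glycolysis (0.0531), unfolded protein response (0.278) and pericytes (0.298) were lost. With the covariate the calls of interferon-stimulated genes (0.0604), mitral and tufted cells (0.192), presynaptic genes (0.174), epithelium support (0.918), oligodendrocyte precursors (0.0604), unfolded protein response (0.069) and pericytes (0.477) were lost, and the last also with camera's trend (0.0829). With the replicate number as a block, 1 gene and 12 lists passed, with 610 higher and 305 lower genes at an unadjusted p. Mice of the same number did not deviate together (correlations of their deviations -0.02, -0.05 and -0.07), so the numbers only name the mice. The variance models without a trend and with robust estimation change only the gene test, since camera uses neither. The count models planned for a table of counts were not run, as the table holds FPKM. Unknown depth limits what can be said of low genes.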

Other observations

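The tests of the Gm24888 and immediate early gene patterns and the counts of other splits were chosen after the results were seen, and the test of vomeronasal receptor genes was chosen after that of TEC position had been seen. Genomic DNA was first to be tested by TEC position, and by a bound fixed before its result that test counted against it. Per mouse the gap by position overlapped between the groups, so no conclusion on genomic DNA is drawn from position. The vomeronasal test took its place, with its bounds fixed before its own result. The bounds for TEC position and for the olfactory sensory neuron relation, and that for NFD 3 alone, were made stricter after their results were seen, where the first 2 had counted in favour of the explanation and the third against it. The relation to mitral and tufted cell markers was picked out of 3 after all had been seen.

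Loci of the class TEC, transcribed regions that the annotation holds without a settled gene model, had a median log2 fold change of 0.26 over 1138 tested loci, with 188 higher and 0 lower at an unadjusted p under 0.05 (limma). Long noncoding RNAs had a median of 0.14 over 923 genes and processed pseudogenes one of 0.13 over 439, while 12833 protein-coding genes had one of -0.00221. Under the 4 other scalings the TEC median was 0.21 to 0.24, that of long noncoding RNAs 0.09 to 0.13, that of processed pseudogenes 0.08 to 0.12 and that of protein-coding genes -0.08 to -0.02. Per mouse, the median deviation of TEC loci was -0.127 ± 0.137 in NFD and 0.138 ± 0.101 in HFD (SD, n = 3 each; exact permutation p = 0.1, the smallest this design allows; 0.1 for long noncoding RNAs and 0.2 for protein-coding genes), with NFD 1 at 0.0293 next to HFD 1 at 0.0293.

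With 3 against 3 mice there are 10 splits, too few for a share under 0.05. The real split gave 1 gene past the threshold and the highest of the other splits 9 (NFD 1, NFD 3 and HFD 2 against the rest), and 9 of the 10 reached the real count. The real call was a short RNA, as were 7 of the 9 genes of the highest other split. At an unadjusted p under 0.05 the real split gave 1227 genes and the highest other 1243, so that 2 of the 10 splits reached the real value. For lists past the threshold the values were 15 and 13, which leaves 1 split of 10 at the real value. For the TEC median they were 0.257 and 0.271, again 2 of the 10.

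The call of Gm24888 rests on about 5 fragments over the 3 HFD mice. Among all short RNAs, the real split had 1 that was listed at 0 in 3 mice and above 0 in the other 3, and 7 of the other splits had at least as many, up to 7, which is consistent with a few fragments that fell in one group by chance. A difference between the diets stays open and was not tested further.

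Only 3 marker lists were compared with the lower immediate early genes across mice, and these genes followed 1 of them. The immediate early list mean differed by -0.401 (SE 0.283, exact permutation p = 0.3), or by -0.172 (SE 0.207) with the olfactory sensory neuron list mean as a covariate. Over the 6 mice, the list mean correlated with that of mitral and tufted cell markers (Pearson r = 0.967, exact permutation p = 0.00139, adjusted over 3 relations 0.00417; Spearman rho = 1, exact permutation p = 0.00278, adjusted 0.00833). The r was 0.961 without the 2 mice farthest from the median. A different share of tissue rich in these cells may therefore account for part of the pattern. Of the 18 markers, 4 also stand in other lists. Olfactory ensheathing cell genes, a list not compared, had means of -0.21, 0.03 and 0.32 in NFD 1 to 3 and 0.05, 0.01 and -0.19 in HFD 1 to 3. These too were highest in NFD 3 and low in NFD 1 and HFD 3. The relation is therefore not shown to be particular to mitral and tufted cells. The relation to olfactory sensory neuron genes (r = 0.858, exact permutation p = 0.0542, adjusted 0.0813; rho = 0.6, exact p = 0.242, adjusted 0.356) rests on 2 mice, as r was 0.565 without NFD 3 and HFD 2, and that to myelin markers was -0.425 (exact permutation p = 0.426, adjusted 0.426; rho = -0.486, exact p = 0.356, adjusted 0.356; r = 0.396 without NFD 1 and HFD 3). Nasal epithelium carried over in NFD 3 alone stays open: without that mouse camera still gave an adjusted p of 0.00802 at its preset correlation, but the list mean differed by -0.175 with an SE of 0.22; the diet itself, neuronal activity and dissection stay open.

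For the higher TEC loci, genomic DNA in the HFD libraries is argued against as the source of a rise of this size. The mean FPKM of 330 vomeronasal receptor genes was 0.00747 higher in HFD, against a median difference of 0.567 FPKM for TEC loci. It was 0.0197, 0.0145 and 0.0152 in NFD 1 to 3 and 0.0258, 0.0218 and 0.0242 in HFD 1 to 3, so HFD was higher in each mouse. Values are printed in steps of 0.1, and 302 of these genes were listed at 0 in all mice. Unlike the TEC loci, they were not filtered to a mean of at least 1 FPKM. Unspliced precursor RNA could be tested by position, since 930 TEC loci lie inside an intron of a protein-coding gene on their own strand. Their median exceeded that of 171 loci outside such genes by 0.0651 (0.27 against 0.20; 95% bootstrap interval over loci 0.0161 to 0.108), in the direction that more precursor RNA would give. That interval covers loci and not mice, and per mouse the gap was 0.0339, -0.108 and -0.0118 in NFD 1 to 3 and -0.0184, 0.0216 and 0.0807 in HFD 1 to 3, with overlap between the groups, so the bound set beforehand was too lenient and the explanation stays open. A response to the diet stays open as well, and the loci outside introns were also higher, at 0.20.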
